A study of Homo sapiens with 2 samples.

How the data were processed

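Total RNA from GIST-T1 cells, 1 culture with control siRNA and 1 with a mixture of 3 HOTAIR siRNAs, was labelled with Cy3 (100 ng per array) and hybridised to one-colour Agilent arrays, per the labels' protocols. Groups were taken from the labels. Per the submitters' processing notes, spots were quantified with Agilent Feature Extraction 10.7, and per the file headers the version was 10.7.3.1 and the array design was annotated on hg19. The deposited values are an intensity per spot on a linear scale, background-subtracted and detrended within each array, with no scaling between arrays, per the file headers. Signals not above background carry a substitute value in these columns, so their differences have no size of their own. The flags of 0 or 1 per spot (well above background, saturated, outlier) are those the authors' scanner software wrote, per the file headers. The submitters' value table holds the same intensity as the deposited scanner files, with a largest relative difference of 0, a linear scale and no centring. Its medians are therefore those of the arrays.

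Each array held 62976 spots, of which 58717 were not controls, for 42405 probes. The median intensity was 87.7 on the control siRNA array and 128 on the HOTAIR siRNA array, and the 75th percentile 800.1 and 1419. Well above background were 33890 and 33241 spots. Outliers of the replicate spot population, 441 and 449 spots, were left out. For 672 probes printed 10 times and measured, the median SD between spots was 0.069 and 0.063 log2 units, which is technical error within an array. Scan and slide were not compared, since each group lay on 1 array and array and group cannot be told apart. Probes of XIST, TSIX and chromosome Y, 182 in all, were left out.

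The main values were log2 of the processed signal minus each array's 75th percentile over non-control spots. Spots of one probe were averaged on the log2 scale. A gene was represented by its brightest probe among those well above background and without outlier flags on both arrays, and 17552 of 34655 genes had one. Where no probe was well above background on one array, a lower bound of the fold was given: the bright array's value against the higher of the dim probe's own value and the lowest signal among probes well above background on that array. The lowest such signals were 39.4 and 61.9. The technical SE of a difference came from the software's signal error on both arrays. Probe names were updated through a RefSeq gene table (GRCh38.p14, used for names only): 24713 probes matched by accession, 1182 by symbol and 466 by synonym, and 15862 kept the name in the files. Coordinates are those of the files, in hg19.

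Before the data were examined, 39 gene lists, the naming rule and most alternatives were fixed. With 1 array per group no test was made, and genes were described by a difference of at least 2-fold. A list's median was placed among the medians of 10000 random lists of the same size matched on mean signal in 20 bins, and a list stood apart at a percentile of at most 1 or at least 99. Percentiles describe these 2 libraries and are not p-values, since genes are not replicates. Named were HOTAIR, the 12 highest and 12 lowest genes measured on both arrays whose measured probes shared a sign and whose name in the files was not an uncharacterised one, the 5 highest bounds in each direction and up to 4 members with the largest difference in each list described. Genes named after their values were seen are marked as such, and KIT and the members of lists with 2 measured genes were also named beyond the rule. One gene that the rule names is not reported here.

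The alternatives were normexp background correction with an offset of 50 on the mean and background signals (limma 3.58.1), quantile, median, loess, detected-probe and spike-in scaling, the submitters' table, no filter on dim probes, a signal of at least 100, the mean of a gene's probes, the probe with the smallest difference, and thresholds of 1.5-fold and 3-fold. A correction for probe GC content and position in the transcript, and the use of the probe nearest the 3′ end, were added after the data were seen. The correction was a quadratic fit that took 12.4% of the variance of differences among probes with a position. Position was counted from the 5′ end of the transcript, since the distance to the 3′ end could not be computed. Probes without a position were left uncorrected, and those for predicted long intergenic RNAs kept their median of −0.28. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and in R 4.3.3.

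The steps were tested on the control siRNA array against a simulated second array made from it with the software's error, with 18641 genes. Detection flags were copied from the control siRNA array, so no gene could fall below background. The changed genes were drawn only from genes with a high control signal. At least 2-fold differences were called for 68 of 68 genes changed 4-fold, 66 of 66 changed 3-fold and 0 of 66 changed 1.5-fold, and for 17 of 18441 unchanged genes under the software's error alone. Of 200 random lists of 25 genes, 5 stood apart on the real arrays and 2 on simulated ones, and 189 of 200 lists shifted by 0.5 log2 units stood apart. The simulation holds no spread between cultures.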

Results

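Gene expression was measured in GIST-T1, a human cell line derived from a gastrointestinal stromal tumour, after transfection with small interfering RNA (siRNA). One culture received a control siRNA and the other a mixture of 3 siRNAs against HOTAIR, a long non-coding RNA transcribed from the HOXC gene cluster. Each received 100 pmol, and RNA was taken after 48 h. Each group held 1 one-colour array, so no difference between the groups has a replicate check and no test or p-value is given. Errors stated here are technical, from the scanner software's error model, and do not include the spread between cultures. The number of arrays limits the precision. Spots well above background made up 57.7% of the gene spots on the control siRNA array and 56.6% on the HOTAIR siRNA array, and 0 were saturated. Differences are HOTAIR siRNA minus control siRNA on the log2 scale, after each array was centred on its 75th percentile.

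The comparison asks which transcripts differ when HOTAIR is targeted. HOTAIR itself was lower in the HOTAIR siRNA library. Its single probe lies on the minus strand of chromosome 12, from 54356661 to 54356720 in hg19, within an exon of the non-coding transcript, at position 1708. The probe, printed as 1 spot, had a signal of 181 with a technical error of 20.2 on the control siRNA array, well above background. On the HOTAIR siRNA array its signal of 13.9, with a technical error of 13.9, was not well above background, so only a bound can be given: HOTAIR was at least 5.18-fold lower. The bound was 3.12-fold with normexp background correction, 3.21-fold with a minimum signal of 100, and 1.37-fold when the arrays were scaled on the spike-in controls.

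Among 17552 genes measured on both arrays, 719 were at least 2-fold higher and 1111 at least 2-fold lower in the HOTAIR siRNA library. Genes here include any name in the files, coding or not. Of the 11928 protein-coding genes, 660 were at least 2-fold higher and 754 at least 2-fold lower. Of 2660 probes for predicted long intergenic RNAs, 26 were higher and 161 lower by this rule. Among genes with characterised names, the higher end was led by API5, an inhibitor of apoptosis (3.48, SE 0.22), RAB8B, a small GTPase of vesicle transport (2.92, SE 0.32), and TAF2, a subunit of the general transcription factor TFIID (2.85, SE 0.21). Next came ARL6IP1, which shapes the endoplasmic reticulum (2.80), XPOT, the tRNA exporter (2.70), CPNE3 (2.70), the bicarbonate transporter SLC4A7 (2.68) and CDK8, a kinase of the Mediator complex (2.63). RTN3 followed at 2.55, the histone chaperone ASF1A at 2.46, the phospholipid scramblase PLSCR4 at 2.39 and the ubiquitin-conjugating enzyme UBE2N at 2.37. At the lower end of the same genes, which leave out the ribosomal RNAs RNA5-8SN5 (−5.22, SE 0.21) and RNA18SN5 (−3.01, SE 0.20), HAPLN2, a protein that links hyaluronan to proteoglycans, differed by −3.23 (SE 0.20) and AQP1, a water channel, by −2.82 (SE 0.21). They were followed by RSU1 (−2.70), the secreted metalloprotease ADAMTS8 (−2.65), the N-glycan branching enzyme MGAT5 (−2.53), ANGPTL4, an inhibitor of lipoprotein lipase (−2.49), and the peptidase DPP3 (−2.47). ITIH3 (−2.36), the activin-binding protein FST (−2.31), LGALS9C (−2.28), RNF222 (−2.28) and INHBB, a subunit of activins and inhibins (−2.27), completed the 12 lowest genes that met the naming rule.

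Second probes did not all give the same size. For AQP1 the other probe gave −2.35. The other probes of API5, CDK8 and RTN3 gave 0.03, 0.17 and 0.10, so these 3 genes were at least 2-fold higher by one probe only. In each the higher probe is the one nearer the 3′ end, starting at position 3049 against 1448 in API5, 1627 against 425 in CDK8 and 2133 against 84 in RTN3, which is the direction of the shift over all transcripts given below. RAB8B, TAF2, ARL6IP1, XPOT, CPNE3, SLC4A7, ASF1A, PLSCR4 and UBE2N had a single measured probe each, so their differences have no check by another probe. These probes start at positions from 1442 (ARL6IP1) to 7326 (SLC4A7), and a shift by position cannot be seen within their transcripts. At the lower end, all named genes but AQP1 likewise had a single measured probe. RSU1 and RNF222 each have another probe nearer the 3′ end that was not well above background on either array. Its signals on the control siRNA and HOTAIR siRNA arrays were 23.2 and 15.2 for RSU1, and 11.1 and 17.5 for RNF222. The other API5 probe is placed on chromosome X in the files, away from the API5 gene. The XPOT probe is placed on chromosome 7, away from the XPOT gene. LGALS9C has near-identical gene copies, and its value is uncertain for that reason. Of 325 genes that passed 2-fold and had several measured probes, 97 passed it in the same direction with every probe. Over all genes the median difference was −0.18, with an interquartile range from −0.49 to 0.18, and the median technical SE was 0.21. Across 21314 probes, which are not independent replicates, Pearson's r between the arrays was 0.968.

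**Figure D1:**
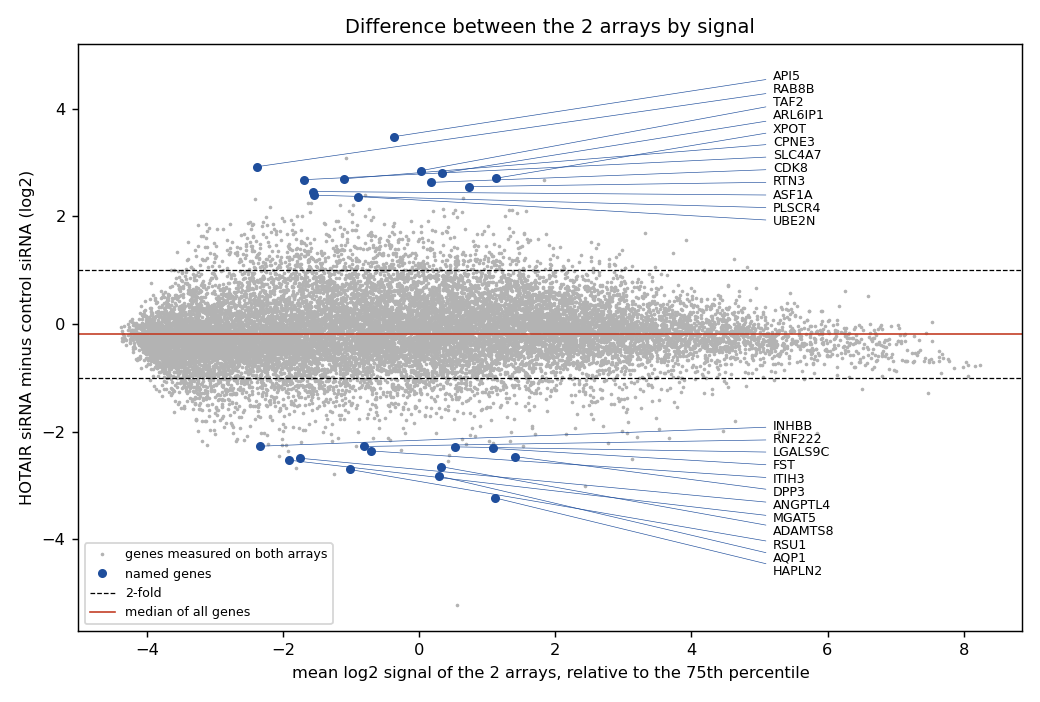
The difference between the libraries (y axis, log2, HOTAIR siRNA minus control siRNA) is plotted against the mean log2 signal of both arrays relative to the 75th percentile (x axis), with 1 point per gene measured on both arrays. Blue points are the 12 highest and 12 lowest genes that met the naming rule, from API5 at 3.48 to HAPLN2 at −3.23; dashed lines mark 2-fold and the red line the median of all genes at −0.18.

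The share of higher genes among those passing 2-fold depended on scaling. It was 39.3% here, 55.5% after quantile normalization, 58.9% after loess centring, 74.8% after scaling on the median and 99.98% after scaling on the spike-ins. The median of all genes was −0.0094, 0.0045, 0.10 and 1.74 under these 4 scalings in turn. Directions below are therefore relative to the 75th percentile, and any gene or list with a difference between −1.92 and 0 lies above 0 under spike-in scaling.

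Some genes were well above background on one array only, 1083 on the control siRNA array and 604 on the HOTAIR siRNA array, and have bounds. CPEB3, which binds the polyadenylation elements of mRNAs, was at least 10.6-fold higher in the HOTAIR siRNA library, the kinase MAP4K3 at least 6.10-fold, PALM2AKAP2 at least 5.51-fold, FAM114A2 at least 5.41-fold and TMEM30CP at least 5.24-fold. In the other direction, the cadherin-related gene CDHR4 was at least 10.8-fold higher in the control siRNA library, SYCP2L at least 6.73-fold, PAGE4 at least 6.11-fold and the matrix protease ADAMTS5 at least 5.47-fold. With a bound of at least 2-fold required, the counts were 242 on the control siRNA array and 80 on the HOTAIR siRNA array.

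Genes of mitosis were higher as a group. The 33 measured genes of the G2/M and mitosis list had a median of 0.41, at the 100th percentile of random lists of the same size matched on signal. In this list 5 genes were at least 2-fold higher, 0 were at least 2-fold lower, and 30 lay above the median of all genes. The topoisomerase TOP2A (1.66), the kinesins KIF20A (1.48) and KIF11 (1.41) and the spindle checkpoint kinase TTK (1.19) were highest. The fifth, CENPE, a kinetochore motor named after its value was seen, was at 1.08. The 31 measured genes of G1/S and DNA replication had a median of 0.14, at percentile 99.87, with RFC3, a subunit of the clamp loader, at 1.71 and MCM10 at 1.35 being the 2 that passed 2-fold. RRM2 was at 0.81 and POLE2 at 0.69. With the mean of all probes per gene this list had a median of 0.052, at percentile 98.78. After a correction for probe GC content and position it was at 0.088, against 0.084 at the 99th percentile of random lists. Random lists were drawn from all measured genes, coding or not. Protein-coding genes as a class were themselves at percentile 100, with a median of −0.11, which places lists of coding genes somewhat higher. The G2/M and G1/S lists both lay above the median of all genes under every scaling tried, of which only quantile and loess scaling could change this.

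Replication-dependent histone genes, whose mRNAs end in a stem-loop rather than a poly(A) tail, were lower as a group, with a median of −1.45 over 23 measured genes, at percentile 0; under spike-in scaling the median was 0.47, against 1.74 for all genes. Of these, 18 were at least 2-fold lower and 0 at least 2-fold higher. H4C5 differed by −2.11, H4C8 by −2.05 and H3C10 by −2.04, or −1.16 by its other probe. H2AC6 was at −2.02 by its brightest probe and at 1.08 by its other probe. Histone genes have near-identical copies, so the values of single members are uncertain. Other RNAs without a poly(A) tail were also lower, with a median of −0.96 over 31 genes in a list drawn up after the values were seen, and −0.49 after a correction for probe GC content and position.

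Interferon response genes had a median of −0.49 over 25 measured genes, at percentile 0.46, and 1.43 under spike-in scaling. In this list 6 genes were at least 2-fold lower and 1 at least 2-fold higher. IFI27 (−2.27), XAF1 (−2.14), the antiviral RSAD2 (−1.35) and the antiviral GTPase MX1 (−1.31) differed most, and the gene in the opposite direction, named after its value was seen, was DDX60 (1.13). Smooth muscle markers had a median of −0.57 over 10 measured genes, at percentile 0.50, and 1.34 under spike-in scaling. The 4 that passed 2-fold were lower: calponin CNN1 (−2.00), the actins ACTG2 (−1.64) and ACTA2 (−1.21), and tropomyosin TPM2 (−1.22).

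Genes of the unfolded protein and integrated stress response had a median of −0.42 over 29 genes, at percentile 0.53, and 1.501 under spike-in scaling. The 4 that passed 2-fold were lower, namely SDF2L1 (−1.42), the endoplasmic reticulum chaperone HSPA5 (−1.37), the stress transcription factor DDIT3 (−1.12) and HERPUD1 (−1.04). After a correction for probe GC content and position, chosen after the data were seen, this list had a median of −0.32 (quartiles −0.75 to −0.12, against −0.78 to −0.10 before) and was at percentile 4.335. The call ended because the median came within the 1st percentile of the random lists, which was −0.39 before and −0.38 after. With the probe of smallest difference the median was −0.38, at percentile 1.15. Genes of cholesterol and fatty acid synthesis had a median of −0.40 over 28 measured genes, at percentile 0.54, and 1.52 under spike-in scaling. Members passed 2-fold in both directions: MVD (−1.68) and the desaturase FADS1 (−1.13) were lower, while MSMO1 (1.08) and HMGCS1 (1.06), both enzymes of sterol synthesis, were higher.

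**Figure D2:**
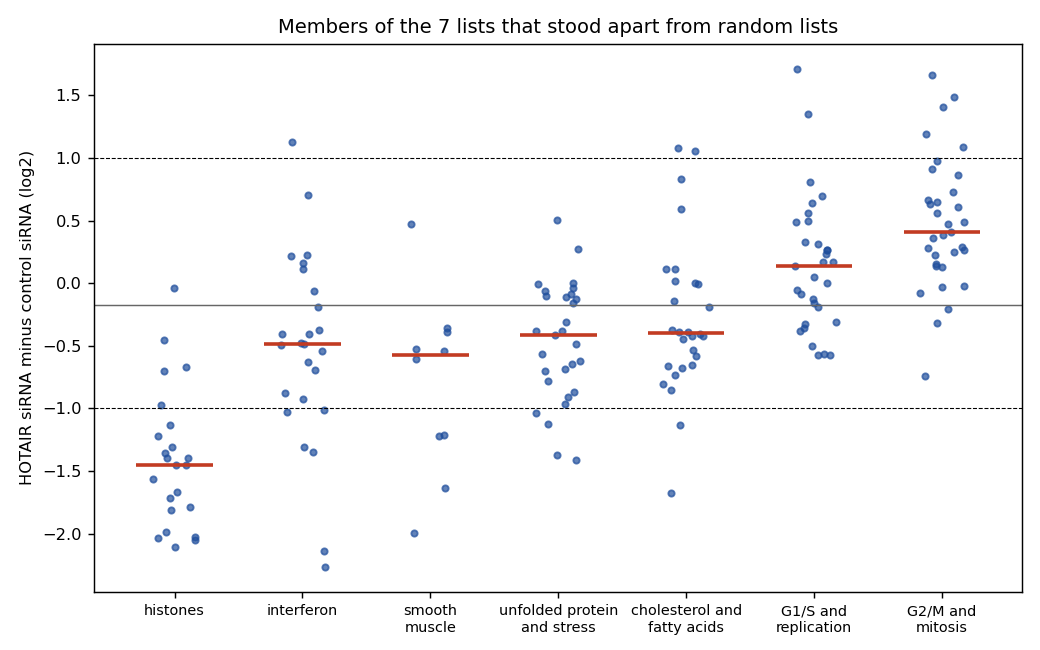
Each point is 1 measured gene of the 7 lists that stood apart from random lists, with its difference in log2 units on the y axis; red bars are list medians, the grey line the median of all genes and dashed lines 2-fold, and sideways position within a list is arbitrary. Histone genes lie lowest, with a median of −1.45, and genes of mitosis highest, with a median of 0.41.

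Lists tied to HOTAIR did not stand apart in the main setting. Those with few measured genes could stand apart only through a large shift. The 1st to 99th percentile of random lists ran from −0.82 to 0.80 for the HOXD cluster, with 5 of 11 genes measured. It ran from −0.84 to 0.84 for genes described elsewhere as lowered by HOTAIR, with 4 of 12 measured. HOTAIR lies within the HOXC cluster, whose 8 measured genes had a median of −0.18, at percentile 52.9; HOXC8 was at −1.53, HOXC10 at −1.06, HOXC4 at −0.26 and HOXC13 at 1.35. The HOXD cluster had a median of −0.31 over 5 measured genes, at percentile 24.2, and none passed 2-fold; HOXD1 was at −0.67, MTX2 at 0.67, HOXD13 at −0.38 and HOXD3 at −0.31. Genes described elsewhere as lowered by HOTAIR had 4 measured members, with a median of −0.31 at percentile 22.9, and 0 passed 2-fold; RBM38 was at −0.52, JAM2 at −0.42 and PCDHB5 at 0.22. Genes described elsewhere as raised by HOTAIR had a median of −0.71 over 6 measured members, at percentile 1.06, and stood apart at percentiles of 0.40 to 0.81 under 4 alternatives. Among these the collagenase MMP1 was at −1.38, MMP3 at −0.98 and SNAI1 at −0.78, while the kinase ABL2 was at 1.38 by its brightest probe and as low as 0.14 by another.

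The subunits of PRC2 and of the LSD1-CoREST complex, which HOTAIR is described as binding, had a median of −0.02 over 17 genes, at percentile 87.5. REST was at −1.0, HDAC2 at 0.68, KDM1A at 0.47 and MTF2 at −0.43. Protocadherins had a median of −0.01 over 15 measured genes, at percentile 81.0, with PCDH1 at −1.13, PCDH18 at −0.88 by its brightest probe and −2.16 by its other, PCDHB10 at 0.58 and PCDHB8 at −0.39.

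Markers of gastrointestinal stromal tumour had a median of 0.07 over 15 measured genes, at percentile 95.7. NKX3-2 was at 1.19, NES at −1.06 (−1.59 by its other probe) and GPR20 at −0.96. ETV1, a transcription factor of these tumours, was at 0.88 by its brightest probe, and its 4 probes ranged from −0.31 to 1.37. KIT, the receptor that drives most of these tumours, was at −0.05 by its brightest probe, which starts at position 4805 of the transcript, and at −2.34 by a probe that starts at position 918. The remaining KIT probe, at position 1778, had a signal of 181 on the control siRNA array and 66.7, not well above background, on the HOTAIR siRNA array, a difference of −2.27 or lower. KIT was thus lower by 2 of its 3 probes, those nearer the 5′ end, and not by the probe nearest the 3′ end. This is the direction of the shift over all transcripts given below. The level of KIT is therefore not settled by these arrays. Targets of KIT and MAPK signalling had a median of 0.15 over 16 measured genes, at percentile 97.54, with SPRED2 at 1.71, ETV4 at −1.53, SPRY2 at 0.79 and SPRED1 at 0.75.

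Genes of the extracellular matrix and of cell adhesion did not stand apart as lists. Extracellular matrix genes had a median of −0.14 at percentile 54.6, and the 4 of 23 measured genes that passed 2-fold were fibronectin FN1 (−1.97, SE 0.35), thrombospondin THBS1 (−1.53, and −2.82 by its other probe), the collagen COL6A2 (−1.21) and SPARC (−1.21). Integrins and adhesion genes had a median of −0.25 at percentile 25.3, and the 4 of 16 that passed were MCAM (−1.52), ITGA10 (−1.20), ITGA11 (−1.18) and ITGA5 (−1.05). TGF-beta and YAP targets had a median of −0.43 at percentile 3.08; AMOTL2 (−1.55), CCN1 (−1.49) and TGFBI (−1.47) were lower and the Hippo kinase LATS2 (2.07) was higher. Among 23 measured p53 targets, with a median of −0.06 at percentile 63.4, 3 were at least 2-fold higher and 0 at least 2-fold lower: CCNG1 (1.91 by its brightest probe and 0.36 by its other), ZMAT3 (1.36) and SESN1 (1.27), with BBC3 at −0.91.

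In the main setting the remaining lists lay between the 1st and 99th percentile. Lists of other cell types had medians of −0.56 for epithelial markers at percentile 5.94, −0.17 for fibroblast markers at 57.2, −0.52 for leukocyte markers at 7.63 and −0.86 for neural and glial markers at 1.02. The last list, with 5 measured genes, stood apart under 7 alternatives, at −1.03 and percentile 0.18 after the GC and position correction. Endothelial markers had 2 measured members, ENG (−0.92) and CDH5 (−0.36), and mast cell markers 2, GATA2 (−0.37) and KIT, too few for a percentile. The HOXA cluster was at −0.13 (percentile 50.9) and the HOXB cluster at −0.24 (percentile 36.0). Apoptosis regulators were at −0.39 (percentile 4.01), NF-kB and inflammatory cytokines at −0.47 (7.75), heat shock genes at 0.018 (95.2), hypoxia and glycolysis genes at −0.31 (10.73) and immediate early genes at −0.35 (17.6). Matrix proteases and inhibitors were at −0.40 (5.44), factors of epithelial-mesenchymal transition at −0.41 (11.3) and Wnt targets at −0.49 (2.765). Cytosolic ribosomal proteins were at −0.20 (92.8), but stood apart under 6 alternatives, and after the GC and position correction their median was 0.011, at percentile 99.99. After the same correction hypoxia and glycolysis genes were at −0.46 (0.24) and matrix proteases and inhibitors at −0.48 (1). The medians of the other lists were −0.28 (20.4) for the mitochondrial respiratory chain, −0.02 (70.7) for the RNA interference machinery and −0.15 (77.9) for housekeeping genes.

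**Figure D3:**
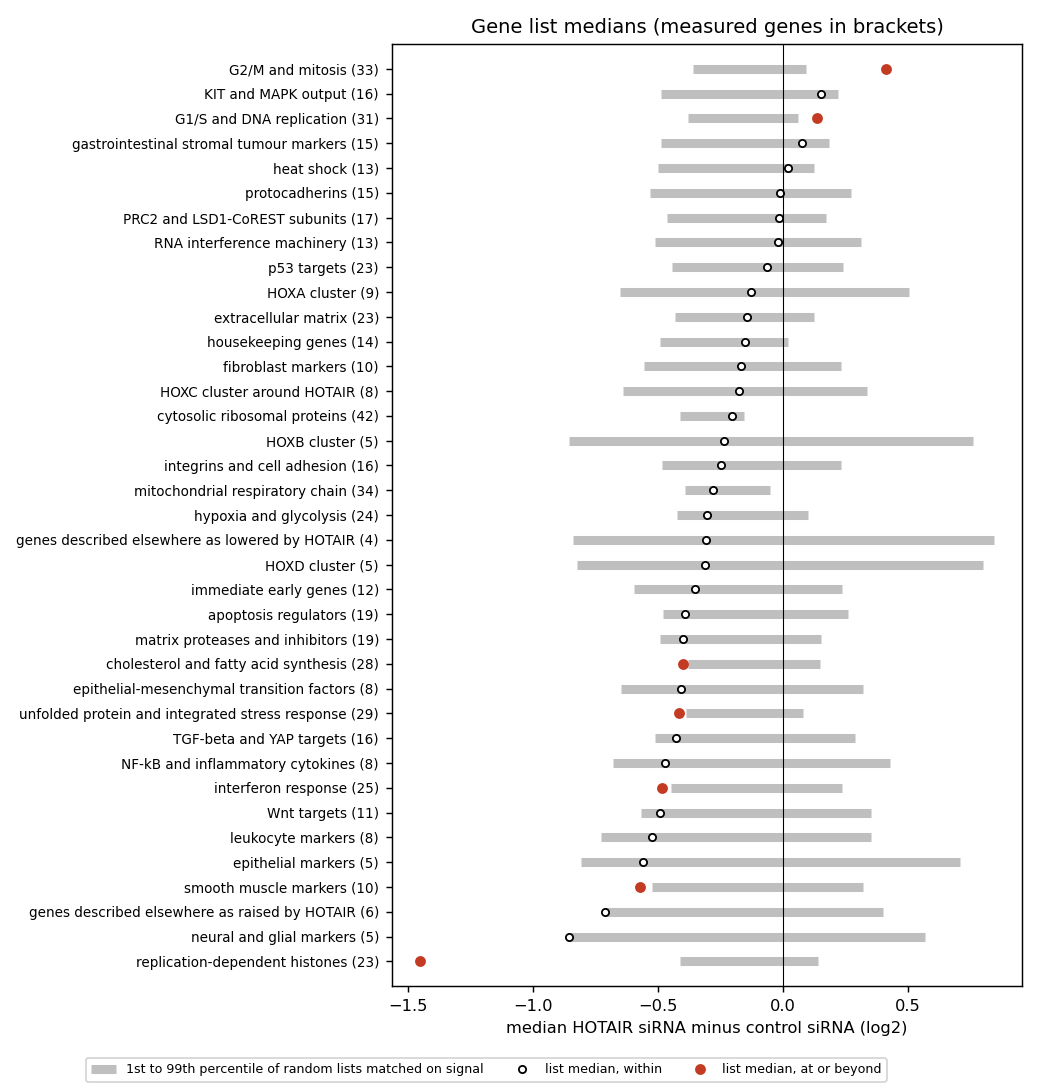
Median difference (x axis, log2, HOTAIR siRNA minus control siRNA) of each of the 37 lists with at least 3 measured genes, with the number of measured genes in brackets; grey bars span the 1st to 99th percentile of 10000 random lists matched on signal. The 7 red points stand apart: histones at −1.45, smooth muscle markers, interferon response, unfolded protein and stress response and cholesterol synthesis lie below their bars, and G1/S and G2/M lie above.

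The position of a probe in its transcript moved with the library. In 1287 transcripts with measured probes over 1000 nt apart, the probe nearer the 3′ end gave a higher difference than the probe nearer the 5′ end in 990 (76.9%), by a median of 0.53 (SD 0.76 across transcripts). In 126 transcripts whose probes lay within 100 nt of each other, the median was −0.03 (SD 0.22). Differences also followed the GC content of the probe, from a median of 0.06 in probes of up to 35% GC to −0.39 in probes above 50%. The 7 spike-in controls above background on both arrays differed by a median of −1.92, from −1.99 to −1.23. The HOTAIR probe has 36.7% GC. A correction for GC content and position, chosen after the data were seen, was applied to the probes with a position in the files. Position was counted from the 5′ end, so a probe of a short transcript was corrected like a 5′ probe of a long one. After it the histone median was −1.05 and the G2/M median 0.41, at percentiles 0 and 100. In the same setting G1/S was at percentile 99.12, interferon response at 0.18, cholesterol and fatty acid synthesis at 0.08 and smooth muscle markers at 0.02.

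**Figure D4:**
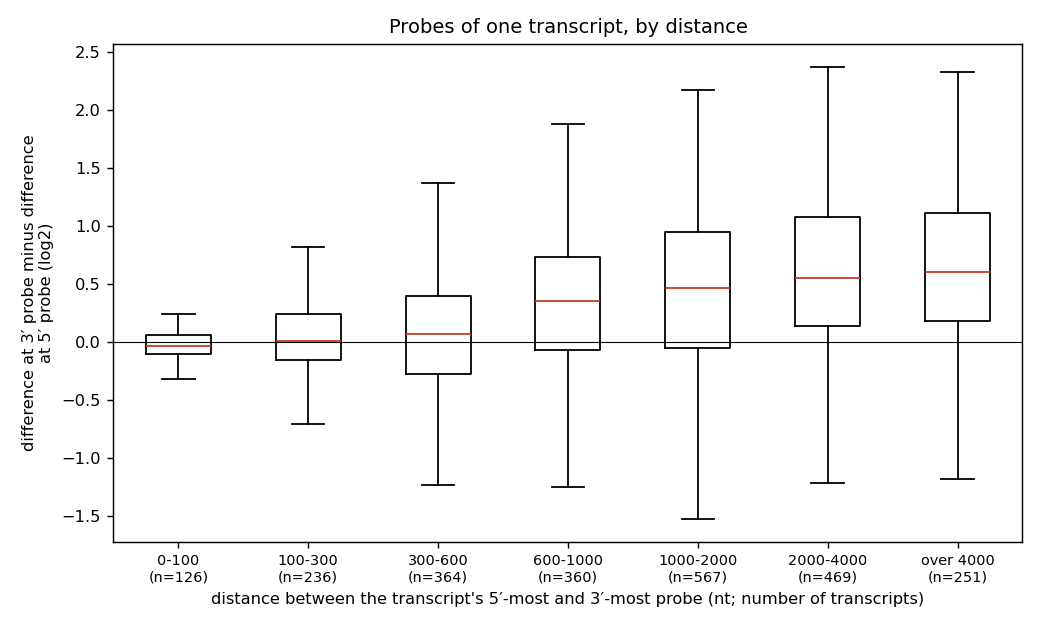
For transcripts with several measured probes, the difference at the 3′-most probe minus that at the 5′-most probe (y axis, log2) by the distance between them in nucleotides (x axis, with the number of transcripts); boxes span the quartiles, red lines are medians, whiskers reach the farthest value within 1.5 box heights, and values beyond are not drawn. The median goes from −0.03 within 100 nt to 0.60 above 4000 nt.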

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

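Most alternatives were planned before the data were examined; the GC and position correction and the probe nearest the 3′ end were chosen afterwards. No paired analysis was possible because each group held 1 array, and for the same reason leaving out an array was not possible. The cause of the shifts between settings was not tested, except where the setting itself sets them (thresholds, filters and a constant added by scaling). Signal over background limits what can be said of HOTAIR and of the genes seen on one array only.

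HOTAIR was lower in every setting. The bounds were 3.12-fold (normexp), 4.33-fold (quantile), 4.26-fold (median scaling), 4.28-fold (loess), 1.37-fold (spike-in scaling) and 3.21-fold (signal of at least 100). In 7 others the bound lay within 1 technical error of 5.18-fold. Of these, only scaling on detected probes could change a bound. The rest leave the signals and flags behind it as they were. Genes at least 2-fold higher and lower numbered 425 and 672 with normexp, 1407 and 474 with median scaling, 1010 and 704 with loess, 16156 and 3 with spike-in scaling, and 1086 and 2842 without a filter on dim probes, where 27.6% were higher. At 1.5-fold they numbered 1947 and 3431, and at 3-fold 150 and 187. Quantile normalization gave 953 and 764, and the correction for GC and position 521 and 1050, of which 486 and 852 were shared with the 719 and 1111. Genes seen on the HOTAIR siRNA array only numbered 944 with a looser flag (positive and significant) and 80 with a bound of at least 2-fold, and on the control siRNA array only 242 with that bound.

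Of the 7 lists that stood apart, 5 did so under all 13 alternatives; the constant scalings among these cannot change a percentile. G1/S was at percentile 98.78 with the mean of probes (median 0.052 against 0.14), and the unfolded protein and stress response at 1.15 with the probe of smallest difference and 4.335 after the GC and position correction (medians −0.38 and −0.32 against −0.42). Another 6 lists stood apart only under alternatives: neural and glial markers in 7 (percentiles 0.18 to 0.97), ribosomal proteins in 6 (99.07 to 99.99), genes described elsewhere as raised by HOTAIR in 4 (0.40 to 0.81), matrix proteases in 3 (0.845 to 1), TGF-beta and YAP targets in 1 (0.68) and hypoxia and glycolysis in 1 (0.24).

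Spike-in scaling turned these lower genes to values above 0: HOXC8 0.39, HOXC10 0.86, MMP1 0.54, PCDH1 0.79, REST 0.92, NES 0.85, ETV4 0.39, RSAD2 0.56, MX1 0.61, SDF2L1 0.50, HSPA5 0.55, DDIT3 0.80, HERPUD1 0.88, MVD 0.24, FADS1 0.78, THBS1 0.39, COL6A2 0.70, SPARC 0.71, MCAM 0.40, ITGA10 0.72, ITGA11 0.74, ITGA5 0.87, AMOTL2 0.37, CCN1 0.42, TGFBI 0.44, ACTG2 0.28, TPM2 0.69, ACTA2 0.70, NORAD 0.70 and MEG3 0.77. H2AC6 was at 1.08 with the probe of smallest difference and with the probe nearest the 3′ end. For named genes, 1106 other values under the alternatives stayed within 1 technical SE and 313 moved further without a called gene changing sign. Many of these outcomes were fixed in advance. The submitters' table holds the same values, and median, detected-probe and spike-in scaling add a constant to every gene. The settings that choose or average probes cannot change a gene with a single measured probe. Named genes dimmer than 100 on either array, such as RAB8B, have no value with a signal of at least 100. The bounds of named genes other than HOTAIR stayed close in 63 values and moved in 54, under normexp, the signal filter and all scalings but that on detected probes. Among the settings where they stayed close, only scaling on detected probes could change a bound.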

Other observations

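Genes in the next paragraphs were named, and the tests chosen, after their values were seen, while the gene lists other than that of RNAs without a poly(A) tail were fixed before. Long non-coding RNAs other than HOTAIR that are annotated in RefSeq did not stand apart as a class. The 281 measured genes of that class in RefSeq had a median difference of −0.23, at percentile 30.5 of matched random lists, with 13 at least 2-fold lower and 4 at least 2-fold higher. The nuclear RNA MALAT1 was at −2.00 (technical SE 0.20). NORAD, a cytoplasmic RNA that binds PUMILIO proteins, was at −1.22, and at −0.74 by its other probe. The imprinted MEG3 was at −1.15 by its brightest probe, and its 3 probes ranged from −1.15 to −0.28. Probes for predicted long intergenic RNAs, 2660 in all, did stand apart, with a median of −0.28, at percentile 0. The 1st percentile of their random lists was −0.26, against −0.29 for the smaller class of 281 genes. A median of −0.28 would not have stood apart there, so these medians do not show that the classes differ. Of the 2660, 161 were at least 2-fold lower and 26 at least 2-fold higher, against 1111 and 719 of all 17552 measured genes. Small nucleolar RNAs, 21 measured, had a median of −0.57, at percentile 0.22; after correction for probe GC content and position they were at −0.42 and percentile 3.19, and no longer stood apart.

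Among genes measured on both arrays, the most negative difference belonged to a ribosomal RNA. RNA5-8SN5 was at −5.22 and RNA18SN5 at −3.01, and the 4 probes of RNA28SN5 ranged from −2.65 to −0.81. In the files, only the RNA28SN5 probe at −2.65 is placed on the same contig as the RNA18SN5 and RNA5-8SN5 probes. Those at −0.98 and −0.81 are placed on chromosome X and that at −2.51 on chromosome 12. The 7SK RNA, RN7SK, was at −2.01 and RMRP at −1.39, while RN7SL1 was at −0.20 and SNORA20 at 0.63.

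The first pattern is the higher difference at the probe nearer the 3′ end of a transcript, by a median of 0.53 in probes over 1000 nt apart. Probe GC content cannot account for all of it: in 322 such pairs with GC within 3 points the median was 0.47 (95% bootstrap interval over transcripts 0.39 to 0.57). Pairs over 1000 nt apart exceeded pairs within 100 nt by 0.56 (interval 0.51 to 0.61), which restates the pattern and would follow from any cause that acts by position. Labelled product that reached less far from the 3′ end in the HOTAIR siRNA library, through RNA integrity or priming, is one such cause. It cannot be told apart from a change in 3′ ends or isoforms through the knockdown with 1 library per group. The 3′ probe gave the higher difference in 76.9% of transcripts with probes over 1000 nt apart. With probes within 100 nt it did so in 42.1%.

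The second pattern is the lower level of histone mRNAs, with a median of −1.45. A smaller share of dividing cells would lower the G1/S genes too. These were at percentile 99.87, with a median of 0.14 against −0.11 for all measured protein-coding genes, and 17 of 31 lay above 0. The list was at percentile 98.78 (median 0.052) with the mean of probes and at 99.12 after the GC and position correction. The G1/S genes were thus not lower, but how far they stood apart depended on the setting. A move of cells from S phase to G2 was not excluded by these values. Correction for probe GC content and position from the 5′ end left a median of −1.05, at percentile 0. As fitted here they are not the whole cause, though the distance to the 3′ end could not be computed. A lower yield of RNA without a poly(A) tail in the HOTAIR siRNA library remains a candidate explanation: 31 other such RNAs had a median of −0.96, also at percentile 0, and −0.49 (percentile 0.06) after correction. It would account for less than the histone shift if histones were affected no more than these RNAs.

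The third pattern is the higher level of mitosis genes, with a median of 0.41. Correction for probe GC content and position left it at 0.41, at percentile 100, though the distance to the 3′ end itself could not be computed. More cells in G2 or mitosis after the knockdown is one hypothesis, with 30 of 33 genes above the median of all genes. It cannot be told apart from a difference between 2 cultures, such as their density at harvest, because each group held 1 library.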
